A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

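Mononucleosomal DNA of Saccharomyces cerevisiae was gel-purified after MNase digestion and sequenced on a Solexa/Illumina instrument, per the labels. There were 5 libraries, 1 per group: BY4741 typical digestion, BY4741 over digestion, and rpb1-1 at 0, 20 and 120 min after medium at 49 C was added to a culture of optical density 0.6 grown at 25 C, to reach 37 C. The labels name the strain of the last 3 RPO21 and their growth protocol names it rpb1-1. A less digested library is named in the series design, but no file of it was among those used here, so it was not analysed.

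The deposited files hold one line per distinct 36-base read sequence with its read count, and the chromosome, position, direction and error value of its alignment, per the file headers. The counts are whole numbers and not normalised. The aligner, its version, the genome build and the treatment of reads with several matches are not given in the sources used here. The position was found to be the 5' end of the read on both strands. Error values are scored differently in the BY4741 and the rpb1-1 files. Reads without a mismatch were therefore taken by a separate cut-off of that value in each strain's files. No genome came with the files. Its bases were rebuilt from the most frequent base of perfectly matching reads, which covered between 80.4% and 97.4% of each nuclear chromosome. By their error values, 82.7% to 92.4% of reads per library had no mismatch, a share not comparable between the strains. Protein-coding genes of the R64 reference table were found in that sequence as open reading frames near their listed place (5412 genes) or by start and stop codon between matched neighbours (307 genes), in all 5719 of 6002. All coordinates are those of the files, whose build is not stated, and R64 served for gene names and for the order and rough place of genes. Of 5257 genes with a standard symbol 5138 were located, and these entered the gene analyses. ACT1 was not among them. Placed features were 248 of 275 tRNA genes, 79 snoRNA and snRNA genes, and the 9 of 16 centromeres whose elements were found in the rebuilt sequence. Retrotransposons were not analysed.

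A dyad was placed 73 bp downstream of the 5' end of each read, and reads were scaled to the total on nuclear chromosomes outside the rDNA (chromosome XII, 451000 to 490500). The +1 nucleosome of a gene was the highest smoothed dyad density (Gaussian SD 20 bp) from 150 bp upstream to 120 bp downstream of the start codon. It was located in a library outside each comparison. That was rpb1-1 at 0 min for the BY4741 libraries and BY4741 typical digestion for the rpb1-1 series. For 0 min with BY4741 typical digestion it was rpb1-1 at 20 min. The nucleosome-depleted region ran from 210 to 90 bp upstream of it, the -1 window from 330 to 211 bp upstream, the +1 window 60 bp either side, and the +2 and +3 windows from 105 to 225 and from 270 to 390 bp downstream. Mid-coding windows ran from 500 bp downstream to 300 bp before the stop codon in genes of at least 1000 bp. Fragment length was the offset between strands, from 100 to 250 bp, with the highest cross-correlation. Shifts are differences of mean dyad position within 60 bp of the nucleosome, with intervals from 100 resamples of reads, and arrays had 200 resamples.

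There were 5 comparisons: over with typical digestion, 20 with 0 min, 120 with 0 min, 120 with 20 min and, as a background, 0 min with BY4741 typical digestion. With 1 library per group no p-value was computed. Ratios carry exact Clopper-Pearson 95% intervals of the 2 read counts, and shares carry exact binomial ones. With a total between 1139123 and 3168326 nuclear reads the density was 94.9 to 264 reads per kb. A gene was called higher or lower at 2-fold or more with an interval that excluded no change and at least 20 reads in the 2 libraries together. Beside each count over all genes under the main settings stands the mean of 100 random splits of the pooled reads. Where a library had 0 reads, a floor of 3 reads for that library gave a nominal fold, which is not an interval bound.

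The 12 gene lists, fixed before the data were examined, were ribosomal protein, ribosome biogenesis, heat shock and stress, glycolysis and fermentation, histone, meiosis and sporulation, other carbon and phosphate sources, proteasome, mitochondrial ribosomal protein, PAU, mating and pheromone response, and RNA polymerase II with its general factors. Each list's median (with 0.5 reads added where needed) was ranked among 10000 random lists of the same size matched on reads, which describes these libraries only. Lists with under 3 measured members were given no value. Codon adaptation used 23 ribosomal protein genes as reference, and all genes of the ribosomal protein list were left out of the 5 groups.

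Named genes followed a rule fixed beforehand. In each of the 3 main comparisons these were the 8 highest and 8 lowest genes of the nucleosome-depleted region by the interval bound nearest 0, the 3 highest and 3 lowest coding regions, up to 2 members per list with the largest size of that bound, and RPO21, ACT1, PMA1, TDH3, ADH1, HSP12, HSP26, HSP82, HSP104, SSA4, PHO5, GAL1, GAL10, RPL3 and CLN2. The text names the members of this set that describe a group best. Genes outside it are said to be chosen after their values were seen.

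The steps were tested on simulated data with 200 changed genes per comparison. Promoter changes of 1.5-fold were called in 14%, 14% and 20% of 50 genes in over with typical digestion, 20 with 0 min and 120 with 0 min, and changes of 4-fold in 62%, 88% and 80%. Unchanged genes were called in 2.46% of 1465, 1.80% of 2228 and 1.65% of 2359. The simulation and the random splits drew reads independently. They hold neither repeated reads from amplification nor variation between libraries, so they can understate how many unchanged genes are called. A simulated +1 shift of 6 bp was measured as a median of 4.82, 3.67 and 3.69 bp, so shifts are understated. Alternatives tried were 1 read per strand and position, the fragment midpoint as dyad, scaling to mid-coding density or within chromosomes, the start codon as anchor, other windows, half-widths, smoothing, read minimums and thresholds, thinning, leaving out shared promoters or chromosome II, reads without mismatch, and GC centring or matching. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.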

Results

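Nucleosome-sized DNA left by micrococcal nuclease (MNase), an enzyme that cuts the linker between nucleosomes, was sequenced from budding yeast in 5 libraries. Each of the 5 conditions had 1 library, so no difference has a replicate check, and every comparison sets those libraries side by side rather than the conditions. The digestion pair came from strain BY4741. A typical digest used 10 uL of MNase and was about 80% mononucleosomal, and an over digest used 15 uL and was about 100% mononucleosomal. The temperature series came from rpb1-1, a strain with a temperature-sensitive allele of RPO21, which encodes the largest subunit of RNA polymerase II. Its libraries were taken 0, 20 and 120 min after a change from 25 C to 37 C. The total was 1160163 reads for typical digestion, 3249965 for over digestion, 2492151 at 0 min, 2099043 at 20 min and 2308347 at 120 min. Between 97.49% and 98.5% of them lay on nuclear chromosomes outside the ribosomal DNA. Intervals are exact 95% intervals of the read counts, and they cover counting error only, because amplified reads are not independent molecules.

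RPO21 carried 19 reads in its nucleosome-depleted region at 0 min, 15 at 20 min and 13 at 120 min, a log2 ratio of -0.11 at 20 min and -0.44 at 120 min. Both intervals included 0. Nucleosome reads over RPO21 do not show whether its product was functional, so they do not check the strain label.

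Nucleosome arrays over genes were sharpest in typical digestion and at 0 min and flatter in the other libraries. The amount of MNase is given for BY4741 only. The ratio of peak to trough density was taken over the first 5 nucleosomes of the average gene. The mean peak, without the first and the last, was divided by the mean of the troughs between all 5. In BY4741 this ratio was 3.77 (3.74 to 3.81) in typical digestion and 1.91 (1.90 to 1.92) in over digestion. In rpb1-1 it was 4.28 (4.25 to 4.31) at 0 min, 2.87 (2.85 to 2.89) at 20 min and 1.86 (1.85 to 1.87) at 120 min. These ratios depend on the fixed dyad offset of 73 bp. With dyads at the fragment midpoint every ratio was higher and that of over digestion rose most. It then stood well above that of 120 min, so the 2 libraries are not shown to be equally flat. The lowest density just upstream of the +1 nucleosome, the first nucleosome of the gene, was 0.204 of the genome mean in typical digestion and 0.306 in over digestion, against 0.338, 0.444 and 0.529 at 0, 20 and 120 min. The spacing of the 5 peaks was 162.25 bp in both BY4741 libraries and 165.5, 166.75 and 168.75 bp at 0, 20 and 120 min. No library was anchored on its own reads. The +1 nucleosome was located at 0 min for the BY4741 profiles and in typical digestion for the rpb1-1 profiles. Differences in nucleosome position between the strains are therefore not excluded from the peak heights.

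**Figure D1:**
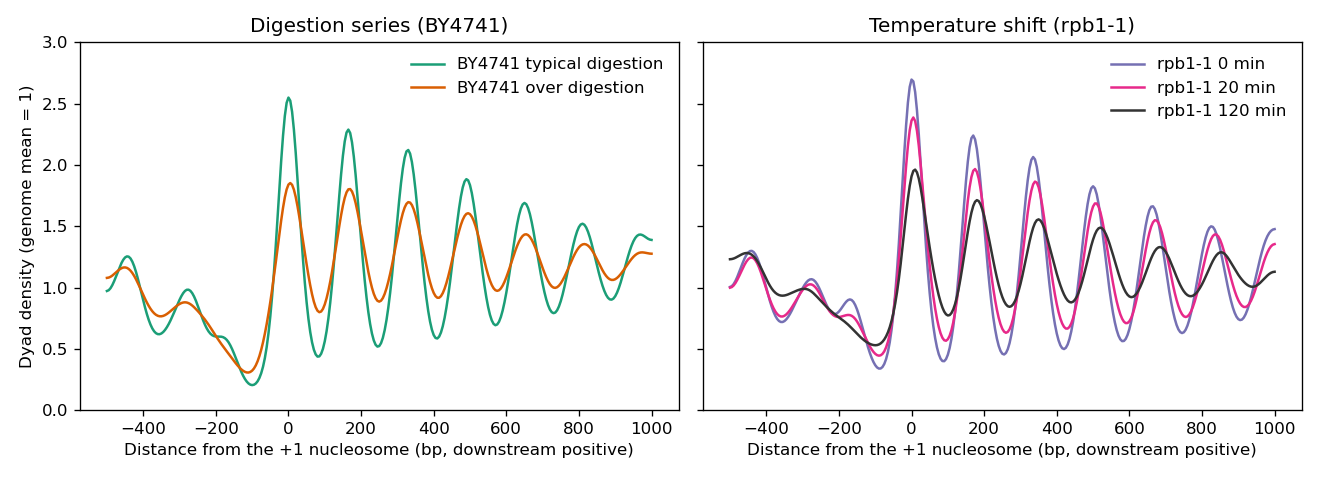
Average dyad density (genome mean = 1, vertical axis) against distance from the +1 nucleosome in bp (horizontal axis), 1 line per library. The peak at the +1 nucleosome was 2.55 in typical and 1.85 in over digestion (left), and 2.70, 2.39 and 1.963 at 0, 20 and 120 min (right).

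The comparison of over with typical digestion sets 2 depths of MNase digestion side by side. URA3, a gene of uracil synthesis, had 42 reads in its coding region in over digestion and 0 in typical digestion under the same strain label, so differences besides digestion are not excluded. The largest promoter gains lay at genes of several pathways. USV1 was 22.3-fold higher (62 against 1 reads). TPS1, which encodes trehalose-6-phosphate synthase, held 93 reads in its nucleosome-depleted region in over digestion against 4 in typical digestion, 8.36-fold higher per nuclear read. Its neighbour MEO1, which faces away from it, was 9.08-fold higher (101 against 4 reads), and the 2 genes may share reads. TSL1, another subunit of the trehalose synthase complex, was named as a member of the heat shock and stress list and was 4.52-fold higher (88 against 7 reads). SDH1, which encodes the flavoprotein of succinate dehydrogenase, had 54 against 2 reads, a log2 ratio of 3.28 (1.36 to 6.36). MHP1, which encodes a microtubule-associated protein, had 54 against 0 reads, 6.47-fold higher against a floor of 3 reads. Its interval began at a log2 ratio of 2.35. Ranked by the interval bound nearest 0, the clearest losses included HFA1, a mitochondrial acetyl-CoA carboxylase (4.68-fold lower, 19 against 32 reads), NSI1, an rDNA silencing factor (4.09-fold lower, 17 against 25 reads), and GRX5, a mitochondrial glutaredoxin (3.82-fold lower, 16 against 22 reads).

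Fragments were shorter in over digestion, 102 bp against 127 bp by the offset between strands. Summed over 5062 genes, the nucleosome-depleted region kept its level, with a log2 ratio of 0.00 (-0.02 to 0.03), though it was -0.18 in a narrower window and 0.12 when measured from the start codon. The +1 nucleosome was lower by a log2 ratio of -0.17 (-0.18 to -0.15), the window at the stop codon was higher at 0.12 (0.10 to 0.13), and the centre of the +1 nucleosome lay 2.46 bp (2.30 to 2.71) further downstream. The +2 and +3 nucleosomes lay 2.11 and 2.22 bp downstream.

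By the median of members with enough reads, none of the 12 gene lists stood apart in the nucleosome-depleted region, where they lay between percentile 14.67 for the seripauperin (PAU) genes and percentile 94.25 for the glycolysis genes among 10000 random lists matched on reads. These medians rest on few members of some lists, 10 ribosome biogenesis and 21 ribosomal protein genes. Summed over 129 and 121 members without a read minimum, these lists were higher, at log2 ratios of 0.70 (0.41 to 1.00) and 0.40 (0.20 to 0.60). In the coding region, 18 glycolysis and fermentation genes had a median log2 ratio of 0.25, at percentile 99.95. The median of 121 ribosomal protein genes was -0.07, at percentile 98.46, and that of 33 mating genes was -0.18, at percentile 1.955. The other 9 lists lay between percentiles 6.945 and 92.36. Glycolysis genes fell to percentile 35.17 against random lists matched on GC content too. Ribosomal protein genes were no longer past the upper percentile threshold under that match, nor with each read start counted at its first read. Mating genes were no longer past the lower percentile threshold with equal totals within each chromosome. For the position of the +1 nucleosome, the 10 lists with enough measured members lay between percentile 2.67 for the mating genes and percentile 82.72 for the ribosome biogenesis genes.

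By the size rule (at least 2-fold, with an interval that excludes no change), 109 of 1655 genes were higher and 119 lower in the nucleosome-depleted region. A random split of the pooled reads gave 23.15 and 21.75 on average. In the coding region 65 of 5058 genes were higher and 20 lower, against 1.44 and 0.5. RPA14, which encodes an RNA polymerase I subunit, was 3.69-fold higher (410 against 40 reads) and SPC25, a kinetochore gene, 3.29-fold higher (522 against 57 reads). PAI3, a proteinase A inhibitor, was 3.73-fold lower (35 against 47 reads). Counting each strand and position only at its first read left 30 higher and 47 lower nucleosome-depleted regions, and 13 higher and 6 lower coding regions.

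The share of reads at RNA genes also moved with digestion. The 248 placed tRNA genes, which RNA polymerase III transcribes, took 0.0805% of nuclear reads (0.0754% to 0.0859%) in typical digestion and 0.180% (0.175% to 0.184%) in over digestion, 2.23-fold higher. The 79 snoRNA and snRNA genes, most of which RNA polymerase II transcribes, were 1.27-fold higher. The rDNA spacer, next to the genes that RNA polymerase I transcribes, took 0.489% and 0.984%. With each read start counted at its first read its log2 ratio turned from 1.01 to -0.28. That count caps densely read loci, so it does not settle the direction.

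Chromosome VIII, and at 20 min chromosome II, held more reads per bp than the rest of the genome in rpb1-1. Chromosome VIII stood at 1.91, 1.84 and 1.82 times the median chromosome at 0, 20 and 120 min, and chromosome II at 1.01, 1.72 and 1.07 times. The other 14 chromosomes lay between 0.842 and 1.05 times in the 3 rpb1-1 libraries. In BY4741 chromosomes II and VIII stood at 1.01 and 0.981 times in typical digestion, and at 0.997 and 0.988 times in over digestion. Raised values on chromosome II at 20 min therefore enter every comparison with that library. The labels speak of culture aliquots, but this excess leaves it open whether the 20 min library came from the same culture as the others, so a difference between cultures is not excluded from 20 against 0 min or 120 against 20 min.

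**Figure D2:**
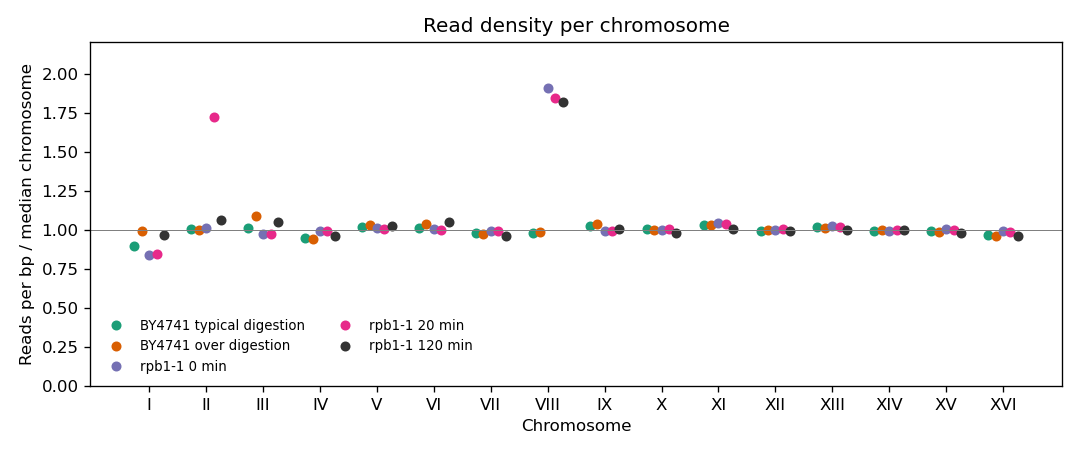
Reads per bp on each nuclear chromosome (horizontal axis) divided by the median chromosome of the same library (vertical axis), 1 point per library. Chromosome VIII stands between 1.82 and 1.91 in the 3 rpb1-1 libraries, and chromosome II at 1.72 at 20 min.

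The comparison of 20 with 0 min asks what happens to nucleosomes soon after the temperature change that inactivates RNA polymerase II in this strain. Ribosomal protein genes gained promoter reads while heat shock and stress genes lost them. The median log2 ratio in the nucleosome-depleted region was 0.45 over 50 measured ribosomal protein genes, at percentile 100 of the random lists, with 8 members higher and 4 lower by the size rule. With equal totals within each chromosome, a setting chosen after seeing the data, it was 0.27, also at percentile 100. RPL9A was 3.82-fold higher (39 against 12 reads) and RPS15 had 18 against 3 reads, a log2 ratio of 2.82 (1.04 to 5.22), whereas RPS29B had 3 against 22 reads, a log2 ratio of -2.64 (-5.02 to -0.91). The median was -0.45 over 60 heat shock and stress genes, at percentile 0, with 2 members higher and 8 lower. HSP104, which encodes a disaggregase, was 2.89-fold lower (10 against 34 reads). TPS1 and SSA3, named as higher members of the list, lie on chromosome II, and relative to that chromosome their log2 ratios of 1.36 and 1.33 became 0.65 (0.08 to 1.24) and 0.62 (-0.15 to 1.44), short of 2-fold.

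The +1 nucleosome of 47 heat shock and stress genes lay a median of 6.78 bp further downstream, at percentile 99.92, against 2.72 bp over 4303 genes. With each read start counted at its first read that median was 4.13 bp, at percentile 89.265. Over all reads of the list the shift was 3.42 bp (1.48 to 4.80), an interval that includes the 2.45 bp over all genes. For promoters measured from the start codon, the loss at heat shock genes shrank to a median of -0.20, at percentile 13.265. HSP12, HSP26, HSP82 and SSA4, which encode heat shock proteins, had log2 ratios of -1.09, 0.02, 0.23 and 0.31, none past the size rule. HSP26 lies on chromosome II, and relative to it stood at -0.69 (-1.43 to 0.04).

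In the coding region, 71 meiosis and sporulation genes had a median log2 ratio of -0.14, at percentile 0, and none of them passed the size rule. The 9 histone genes had a median of 0.45, at percentile 99.84, and 37 proteasome genes 0.08, at percentile 99.77. Counting read starts at their first read took the histone genes to 0.16, at percentile 88.7, and the proteasome genes to 0.05, at percentile 95.465. The other 9 lists lay between percentiles 9.63 and 95.815 there. In the nucleosome-depleted region the other 10 lists lay between percentile 7.965 for the histone genes and percentile 68.855 for genes of other carbon and phosphate sources. For the +1 position the 10 other lists with enough measured members lay between percentiles 3.9 and 95.205.

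The extremes by the named-gene rule included several chromosome II genes. OM14, which encodes a mitochondrial outer membrane protein, was 6.82-fold higher (29 against 5 reads), PDX3, a vitamin B6 enzyme, 3.96-fold higher (64 against 19) and CDC28, the cyclin-dependent kinase gene, 3.26-fold higher (61 against 22), all on II. Relative to that chromosome their log2 ratios were 2.06, 1.28 and 0.99. SUR2, which encodes a sphingolipid hydroxylase, was 4.94-fold higher (21 against 5 reads) and SAG1, which encodes alpha-agglutinin, 4.41-fold higher (30 against 8 reads). HRK1, which encodes a kinase of the plasma membrane proton pump, was 5.10-fold lower (8 against 48), VPS74, a Golgi gene, 5.53-fold lower (6 against 39) and MSS11, which encodes a transcription factor, 4.74-fold lower (7 against 39). AAH1, the adenine deaminase gene, had 3 against 24 reads, a log2 ratio of -2.77 (-5.14 to -1.05).

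Over all genes the changes at 20 min were small. The nucleosome-depleted region had a log2 ratio of -0.07 (-0.08 to -0.05), or -0.18 in a narrower window, and the +1 nucleosome -0.07 (-0.07 to -0.06). The +1, +2 and +3 nucleosomes lay 2.45, 2.49 and 2.08 bp downstream. Fragments measured 127 bp at 20 min and 136 bp at 0 min. The size rule called 71 of 2447 nucleosome-depleted regions higher and 139 lower, against 24.11 and 26.78 for a random split, and 36 of the 71 were on chromosome II. It called 20 of 4957 coding regions higher, 18 of them on chromosome II, and 1 lower, against 0.73 and 0.54 for a random split. The 3 highest coding regions by rule were those of CMD1, the calmodulin gene (2.57-fold), MAL33 (2.15-fold) and PCS60 (2.10-fold), all on chromosome II. Without chromosome II genes, but scaled to totals that include that chromosome, 35 nucleosome-depleted regions and 2 coding regions were higher. Counting each strand and position at its first read left fewer calls in both regions, nearer the means of a random split.

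The comparison of 120 with 0 min asks how the map of this strain looks after a long stay at 37 C. No wild-type library was shifted, so effects of heat and of polymerase loss are not separated at either time. Ribosomal protein promoters gained reads most clearly. The median log2 ratio of 61 measured members was 1.03, at percentile 100, and 29 were higher and 9 lower by the size rule. RPS1B was 7.72-fold higher (115 against 16 reads), RPS0B had 51 against 3 reads (log2 ratio 4.19, 2.56 to 6.52), and RPS0A and RPS18A had log2 ratios of 2.62 (1.94 to 3.36) and 2.34 (1.57 to 3.19). RPL16A and RPS4B went the other way, at -1.77 (-2.83 to -0.83) and -2.09 (-3.13 to -1.17). RPS0A, RPS18A, RPL16A and RPS4B were chosen after their values were seen. Summed over 109 located members without a read minimum, the ratio was 1.76-fold (log2 0.81, 0.71 to 0.91), against 1.32-fold (log2 0.40, 0.20 to 0.60) over 121 members in over against typical digestion.

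Ribosome biogenesis and meiosis genes lay at opposite ends of the random lists for the median shift of the +1 nucleosome. The median was 10.9 bp over 80 ribosome biogenesis genes, at percentile 100, and 68 of them moved downstream. The median was -2.08 bp over 45 meiosis and sporulation genes, at percentile 0.08, against 5.30 bp over 3357 genes. With each read start counted at its first read, these medians were 8.58 bp at percentile 96.91 and 0.05 bp at percentile 4.02. Taken over all their reads, ribosome biogenesis genes moved 9.78 bp (8.55 to 10.9) and meiosis genes 0.09 bp (-1.25 to 1.36). In over against typical digestion the same sums were 4.05 bp (2.57 to 5.22) and -0.04 bp (-1.64 to 1.36), and that of ribosome biogenesis genes was 1.64 bp with each read start counted at its first read, against 1.70 bp over all genes. Over all their reads at 120 min, 5 PAU genes moved 17.05 bp (9.50 to 23.3). Against this stood 11.2 bp (2.78 to 22.6) over 4 PAU genes in over digestion, which became -2.48 bp at the fragment midpoint. Genes of other carbon and phosphate sources moved -1.10 bp (-3.32 to 1.03) at 120 min, which turned to 1.10 bp at the midpoint.

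**Figure D3:**
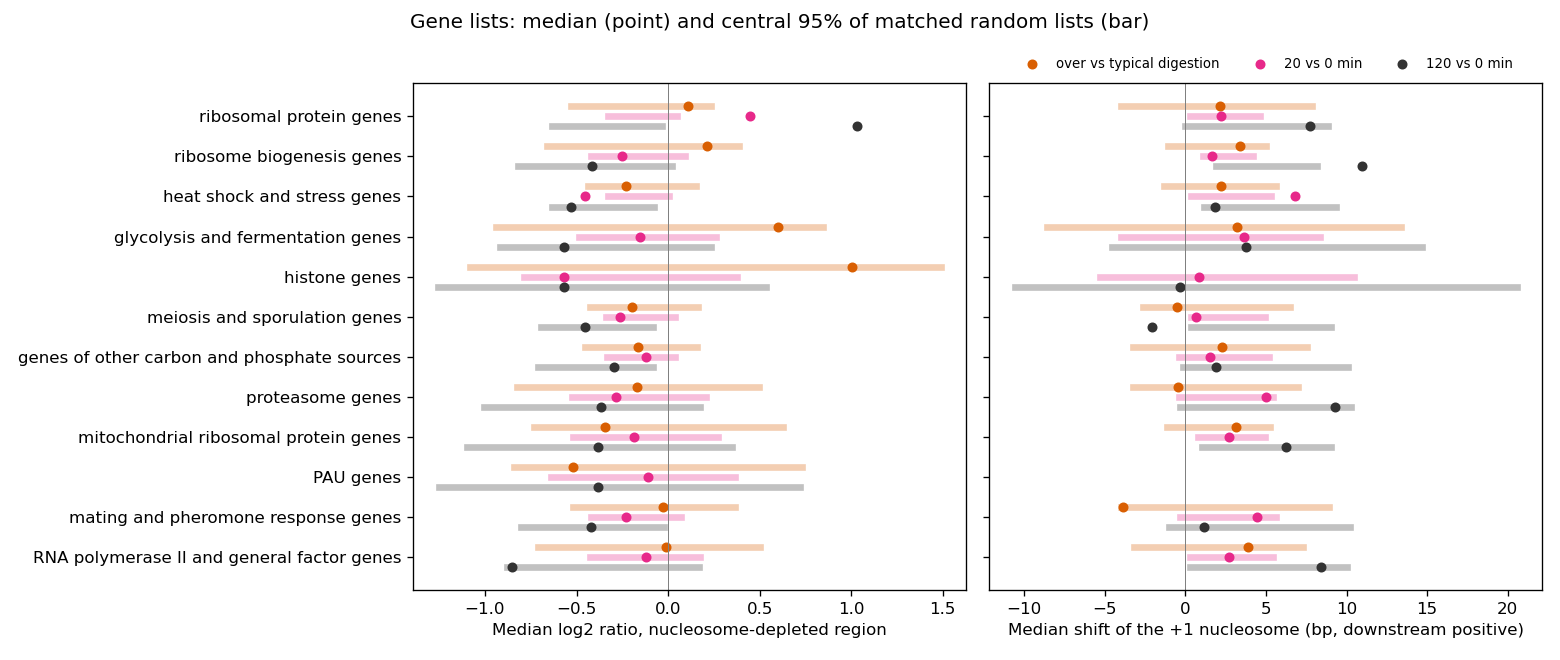
Median log2 ratio of the nucleosome-depleted region (left) and median shift of the +1 nucleosome in bp (right) for each of 12 gene lists in 3 comparisons, with bars for the central 95% of random lists matched on reads. Ribosomal protein genes stand at 0.45 at 20 min and 1.03 at 120 min (left), and ribosome biogenesis genes at 10.9 bp at 120 min (right).

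The largest promoter gains at 120 min lay at genes of several pathways. SPL2, which encodes a regulator of phosphate uptake, was 13.4-fold higher (237 against 19 reads), and PHO4, the transcription factor of the phosphate response, had 63 against 1 read, a log2 ratio of 6.08 (3.55 to 11.4). BXI1, on chromosome XIV from 58898 to 59791, was 31.8-fold higher (148 against 5 reads), and SLA2, which encodes an endocytic actin-binding protein, 12.6-fold higher (153 against 13). MIP1, the mitochondrial DNA polymerase gene, and VMA4, a vacuolar ATPase gene, lie next to each other on chromosome XV and were 17.4-fold and 17.01-fold higher. They face apart and had 97 against 6 and 95 against 6 reads. Their windows may hold largely the same reads, so these are not 2 separate gains. Named as members of the heat shock and stress list, TPS1 was 8.06-fold higher (285 against 38 reads) and XBP1, which encodes a stress-induced repressor, 6.45-fold higher (144 against 24). As lists, 59 heat shock and stress genes had a median of -0.53, at percentile 13.38, with 8 members higher and 14 lower, and 43 genes of other carbon and phosphate sources -0.30, at percentile 79.38, with 6 higher and 7 lower. Summed over all located members the ratios were 0.15 (0.06 to 0.25) over 68 and 0.21 (0.10 to 0.32) over 48 genes, but a single gene carried each sum, and without TPS1 and SPL2 they were -0.06 (-0.16 to 0.04) and -0.03 (-0.14 to 0.09). These genes were left out after their values were seen.

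Promoter losses at 120 min outnumbered gains. CDC23, which encodes a subunit of the anaphase-promoting complex, was 6.05-fold lower (16 against 104 reads), IST2, which encodes a tether between endoplasmic reticulum and plasma membrane, 10.9-fold lower (4 against 47), and PAP2, a nuclear poly(A) polymerase gene, 10.5-fold lower (4 against 45). ISU1, which encodes an iron-sulfur cluster scaffold, had 0 against 20 reads, 6.20-fold lower against the floor of 3 reads. The bound of its interval nearest 0 was a log2 ratio of -2.20. Genes of RNA polymerase II and its general factors had a median of -0.85 over 13 measured members, at percentile 3.85, with 5 lower and none higher. Among these, TAF4, a TFIID subunit gene, was 3.86-fold lower (14 against 58 reads) and RPB4, a polymerase II subunit gene, 4.65-fold lower (7 against 35). The size rule called 271 of 2565 nucleosome-depleted regions higher and 560 lower, against 26.05 and 25.76 for a random split. Counting each strand and position at its first read left 125 and 242.

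In the coding region, 19 glycolysis and fermentation genes had a median of 0.60, at percentile 99.99, 68 heat shock and stress genes 0.13, at percentile 99.97, and 4 PAU genes 0.76, at percentile 99.69. The median was -0.24 for 71 meiosis genes, at percentile 0.33, and -0.25 for 32 mating genes, at percentile 2.06. Against random lists matched on GC content too, glycolysis, heat shock, PAU and meiosis genes lay at percentiles 46.605, 29.53, 56.455 and 25.145. Mating genes rose above percentile 2.5 with each read start counted at its first read, and with equal totals within each chromosome. The size rule called 262 of 4958 coding regions higher and 35 lower, against 0.51 and 0.64 for a random split. SMX3, which encodes a spliceosomal Sm protein, was 7.52-fold higher (189 against 27 reads), and HOT13, which encodes a mitochondrial intermembrane space protein, 3.64-fold lower (33 against 129). Counting each strand and position at its first read left 127 and 7, and centring by the GC content of the coding region 13 and 54. The other 7 lists lay between percentiles 30.0 and 96.395 in the coding region. The other 11 lists lay between percentiles 3.85 and 79.38 in the nucleosome-depleted region. The 9 other lists with enough measured members lay between percentiles 5.64 and 93.51 for the +1 position.

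Over all genes, the nucleosome-depleted region had a log2 ratio of -0.10 (-0.11 to -0.08), but 0.13 (0.11 to 0.14) when measured from the start codon. The +1 nucleosome was lower at -0.22 (-0.23 to -0.21) and the +2 and +3 nucleosomes at -0.12 and -0.13. The +1 nucleosome lay 4.54 bp (4.41 to 4.71) downstream, the +2 nucleosome 3.42 bp and the +3 nucleosome 1.80 bp. In the average profile of 3160 genes, the +1, +2 and +3 peaks lay at 1, 170 and 335 bp at 0 min. At 120 min they lay at 9, 181 and 350 bp, so the displacement of peaks did not shrink into the gene. Mean positions within 60 bp understate shifts, so their fall from +1 to +3 does not show a fading shift. Fragments measured 118 bp at 120 min, with a range of 106 to 118 bp over resampled reads.

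Coding-region ratios at 120 min went with those of over digestion across genes. Across 4921 genes, which are not independent replicates, the coding log2 ratios of the 2 comparisons, which share no library, had Pearson r = 0.754 and Spearman rho = 0.666. Of the 62 genes higher in over digestion and the 258 higher at 120 min, 58 were shared, where independent lists would share 3.25. Of the 17 lower in over digestion and the 35 lower at 120 min, 2 were shared, against 0.121. In the nucleosome-depleted region the relation was weaker, with r = 0.372 over 1445 genes, and 37 higher and 36 lower genes were shared where 7.37 and 19.5 would be by independent lists. For the 20 min changes r with digestion was 0.0462 in the nucleosome-depleted region and 0.0458 in the coding region. In the former, 8 higher and 5 lower genes were shared, against 2.17 and 5.12 for independent lists. The GC content of the coding region had r = 0.503 with the ratio of over to typical digestion and r = 0.717 with the ratio of 120 to 0 min.

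**Figure D4:**
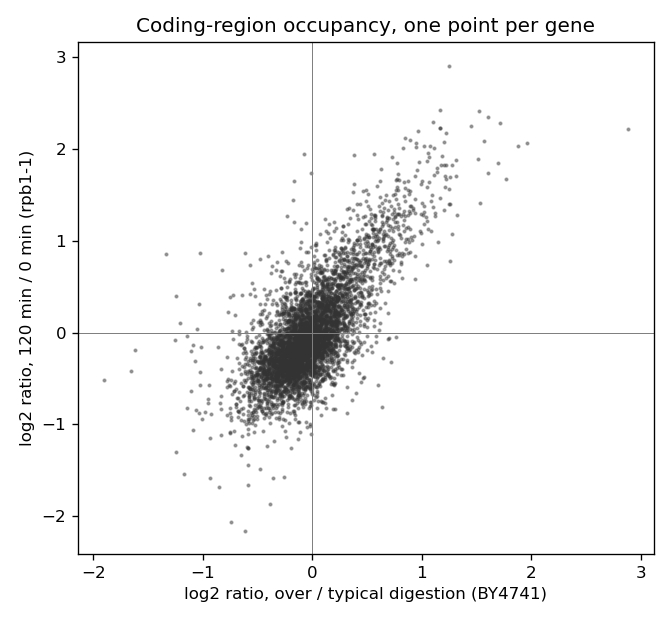
Log2 ratio of coding-region reads in 120 against 0 min (vertical axis) against that in over against typical digestion (horizontal axis), 1 point per gene. The 2 comparisons share no library, and r across 4921 genes is 0.754.

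Changes at 20 and 120 min share the 0 min library, which ties them together by construction. Across 2347 genes the nucleosome-depleted region had r = 0.457, against 0.470 simulated with no effect, and a covariance of 0.269 against 0.0941. When the 0 min reads were split at random between the 2 comparisons, r was 0.267 and the covariance 0.184.

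Between 20 and 120 min, ribosomal protein promoters kept rising, with a median log2 ratio of 0.43 at percentile 100, and heat shock and stress genes rose relative to matched lists, with 0.16 at percentile 98.83. Over summed reads of 68 heat shock and stress genes the log2 ratio was 0.43 (0.33 to 0.54) between 20 and 120 min, after -0.28 (-0.39 to -0.17) at 20 against 0 min. Without TPS1 these sums were 0.29 and -0.35. Both comparisons hold the 20 min library, on opposite sides, so a deviation of that library alone could give this fall and rise. Against random lists matched on GC content too, the percentile of the heat shock list was 97.325. Genes of RNA polymerase II and its general factors had a median promoter ratio of -0.91 at percentile 0.39, and the other 9 lists lay between percentiles 44.655 and 91.24. Median +1 shifts were 10.6 bp for ribosome biogenesis genes (percentile 100), 8.27 bp for ribosomal protein genes (99.88), -7.09 bp for meiosis genes (0) and -2.29 bp for genes of other carbon and phosphate sources (2.22), with 7 other lists between percentiles 2.945 and 58.68. With each read start counted at its first read, ribosome biogenesis genes lay at percentile 95.45, ribosomal protein genes at 88.515, meiosis genes at 28.255, the carbon and phosphate list at 13.99, and the polymerase II promoters at 4.99. Coding medians were 0.21 for heat shock, 0.68 for glycolysis and 1.08 for 4 PAU genes (percentiles 100, 100 and 99.97), which became percentiles 80.03, 76.585 and 90.4 with GC matching, and -0.23 for mating genes (2.33). The other 8 lists lay between percentiles 14.45 and 95.14. The size rule called 261 of 2480 nucleosome-depleted regions higher and 368 lower, against 29.11 and 29.65 for a random split. It called 244 of 4956 coding regions higher and 93 lower, against 0.65 and 0.69. The +1 nucleosome lay 2.09 bp (1.89 to 2.26) further downstream, and its log2 ratio was -0.15 (-0.16 to -0.14).

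Groups of genes by codon usage differed by small amounts. Codon adaptation to 23 ribosomal protein genes served as a proxy for transcription. By it, 4733 genes outside the ribosomal protein list were put in 5 equal groups. The difference in median +1 shift between the highest and the lowest group was -1.07 bp (-2.42 to 0.13) in over against typical digestion, 0.45 bp (0.03 to 1.54) at 20 min and -1.04 bp (-1.87 to 0.67) at 120 min. These intervals come from resampled reads and are not reliable, since that of 120 against 20 min (-2.120 to -0.38) left out its own value of -2.123 bp. In the nucleosome-depleted region the highest group had log2 ratios of 0.03 (-0.02 to 0.08), -0.12 (-0.15 to -0.09) and -0.15 (-0.18 to -0.12), against -0.01 (-0.06 to 0.04), -0.05 (-0.08 to -0.01) and 0.01 (-0.03 to 0.04) in the lowest group. Over coding regions at 20 min the highest group stood at 0.06 (0.05 to 0.07) and the lowest at 0.0094 (0.0013 to 0.017).

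Among other loci, the tRNA genes were 1.06-fold and 1.05-fold higher at 20 and 120 min than at 0 min. The direction at 120 min turned with each read start counted at its first read. The rDNA interval took 0.455%, 0.587% and 1.19% of nuclear reads at 0, 20 and 120 min, 2.61-fold higher at 120 min. With each read start counted at its first read, which caps densely read loci, its log2 ratio was -0.08 at 20 min and 0.30 at 120 min. The 9 located centromeres, where a specialised nucleosome sits, were lower at 120 min, at a log2 ratio of -0.36 (-0.46 to -0.25). Chromosome ends took 2.76% of reads at 0 min, 2.79% at 20 min and 2.58% at 120 min.

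As a background, the 0 min rpb1-1 library was set beside BY4741 typical digestion, 2 libraries that differ in strain and handling. Their files also score alignment errors differently, so a difference in alignment is not excluded from these ratios. Ribosomal protein promoters were higher in rpb1-1, with a median log2 ratio of 1.41 over 38 members at percentile 100 and 22 members higher by the size rule. The 10 measured histone genes had a median coding ratio of -1.24 at percentile 0.01. The nucleosome-depleted region of all genes was higher, at 0.49 (0.47 to 0.51), with 289 of 1687 genes higher, 64 of them on chromosome VIII, and 21 lower. A random split gave 24.54 and 21.53, so the lower calls did not exceed it. In the coding region 72 of 5012 genes were higher, 56 of them on chromosome VIII, and 80 lower, against 1.81 and 0.73 for a random split.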

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

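Here the tests of base composition, and those by codon adaptation, were chosen before their results were seen, and the rest only afterwards.

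The 2-micron plasmid, which yeast carries in many copies, was not among the classes of loci in the design and drew reads in every library. Relative to nuclear reads its share was 1.36% (1.33% to 1.38%) in typical digestion, 1.51% (1.499% to 1.53%) in over digestion, 2.08% (2.06% to 2.10%) at 0 min, 0.886% (0.873% to 0.899%) at 20 min and 0.854% (0.842% to 0.866%) at 120 min. These shares are given because the plasmid had not been planned as a class. No limit was set for them, and no library served as a control. With each read start counted at its first read, the ratio of over to typical digestion changed direction. That count caps so densely read a plasmid and does not test the direction.

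Base composition as the whole reason for the gain of ribosomal protein promoters at 120 min is argued against by the percentile of 100 that remained against random lists matched on GC content. A loss of polymerase function at 37 C could underlie the gain, but the percentile of 100 at 20 min does not test it, as both time points share the 0 min library and no wild-type library was shifted to separate polymerase loss from heat. A first test of deeper digestion, the percentile of 88.73 over 21 members in over digestion, spoke against it and was replaced after it was seen, because the 19 members with enough reads in both comparisons had medians of 0.14 and -0.05 and so did not carry the gain. In the test that replaced it, summed reads of 121 members were higher in over digestion, at a log2 ratio of 0.40 (0.20 to 0.60) against 0.81 (0.71 to 0.91) over 109 members at 120 min, so digestion stays open for part of the gain. The design cannot part the time point from the digestion depth of its only library.

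A fixed dyad offset on shorter fragments as the whole reason for the downstream shift of the +1 nucleosome at 120 min is argued against by a shift of 4.86 bp at the fragment midpoints. For deeper digestion the planned test gave a ratio of 1.03 between the codon-group differences of the 2 comparisons, which says nothing because both intervals include 0 and the resampling behind them is itself unreliable, as 1 such interval left out its own value. Loss of transcription may also contribute, but the highest codon group differed from the lowest by -1.04 bp (-1.87 to 0.67). The bound written beforehand counted any interval reaching 0 against it, and its verdict was changed after the result was seen, because an interval that includes 0 argues neither way and codon usage is only a proxy for transcription. Both explanations stay open, and the gene lists did not decide. Ribosome biogenesis genes moved 9.78 bp at 120 min and 4.05 bp in over digestion. The latter was only 1.64 bp with each read start counted at its first read, against 1.70 bp over all genes. Genes of other carbon and phosphate sources moved -1.10 and 3.69 bp, but 1.10 and 1.17 bp at the fragment midpoint.

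Chromosome VIII in rpb1-1, and chromosome II at 20 min, held more reads than the rest. An added copy of the whole chromosome in the culture, or in most of its cells, is a candidate explanation, since at least 92.1% of their 20-kb bins lay above 1.5 times the median. Base composition is argued against, as 0.214% of bins elsewhere with the GC content of chromosome II did so at 20 min. Deeper digestion is argued against by a density of 0.997 times the median at most in over digestion. No other biological explanation was tested.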

How the results depend on the processing

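Choices of scaling, anchor, window, read starts, smoothing, thinning and thresholds were fixed before the data were examined. Settings by chromosome, GC content, mismatch, search range, the fragment midpoint for gene lists and codon groups, leaving out single list members, and repeats of the named genes were chosen after seeing the data. Among values that answer a comparison, 188 stayed within their interval or on their side of the threshold, 115 moved, 15 lost their place past a threshold and 6 changed direction. Among other reported values these numbers were 253, 123, 13 and 17. The gain of ribosomal protein promoters stayed past the upper percentile threshold in every alternative run at 20 min (99.81 to 100) and at 120 min (100). The +1 nucleosome lay downstream in all alternatives run for the 3 main comparisons. No paired analysis was possible because each condition has 1 library and no numbers link libraries. Counts limit single promoters. Simulated 2-fold changes of promoter reads were called in 38% of genes for over against typical digestion, 34% at 20 min and 38% at 120 min, and 3-fold changes in 68%, 82% and 74%. Except where a sentence names a reason, the cause was not tested.

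Counting each strand and position at its first read removes repeated reads, which made up 34.4% of the over digestion and 16.1% of the typical digestion library. It left 30 higher and 47 lower nucleosome-depleted regions in over against typical digestion, 37 and 58 at 20 min, and 125 and 242 at 120 min. In the coding region it left 13 and 6, 2 and 0, and 127 and 7, and 1 of the extreme coding genes named at 20 min stayed past the size rule. The log2 ratio of the nucleosome-depleted region became 0.10, -0.0291 and -0.0609 in over against typical digestion, at 20 min and at 120 min, that of the +1 nucleosome -0.22, -0.0452 and -0.18, and that of the -1 nucleosome at 20 min -0.015. The +1 shift became 1.70, 2.19 and 3.77 bp. Peak-to-trough ratios became 3.23, 1.58, 3.42, 2.39 and 1.60, and fragments 100 bp in over digestion and 127 bp at 0 min. The rDNA interval turned to -0.28 and -0.0820 in over against typical digestion and at 20 min and became 0.30 at 120 min. The 2-micron plasmid turned to -0.44 in over against typical digestion. Its 47930 and 15439 reads in those libraries exceed the read starts that its 6318 bp can hold. This count therefore caps its share and does not test the direction. The rDNA interval, also densely read, may be capped likewise. The tRNA genes became 0.88 there and turned to -0.0212 at 120 min, where the snoRNA and snRNA genes turned to -0.0093. The median +1 shift of meiosis genes turned positive against 0 min, at percentile 4.02, and against 20 min, at percentile 28.255. Lists no longer past a threshold were heat shock +1 shift (89.265), histone (88.7) and proteasome (95.465) coding at 20 min, mating coding (4.2) and ribosome biogenesis +1 shift (96.91) at 120 min, and ribosomal protein coding in over digestion (90.33). For codon groups in over against typical digestion, the highest group had a promoter ratio of 0.14 and the shift difference was -3.16 bp. The promoter similarity of over digestion with 120 against 0 min fell to r = 0.245, and with 120 against 20 min to 0.237.

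Placing dyads at the midpoint of each library's measured fragment gave a +1 shift of 1.26 bp in over against typical digestion and 4.86 bp at 120 min. Peak-to-trough ratios were 4.15 in typical and 3.08 in over digestion, and 4.61, 3.24 and 2.14 at 0, 20 and 120 min. Spacing in over digestion was 161.75 bp. The +1 nucleosome had -0.0729, -0.0502 and -0.18, and in over against typical digestion the -1, +2 and +3 windows turned to 0.0014, 0.0084 and 0.0052. The nucleosome-depleted region had -0.0584 at 120 against 0 min and turned to 0.0021 at 120 against 20 min.

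Scaling to equal median mid-coding density raises every log2 ratio of a comparison by the same amount, so values near 0 turn by construction. The nucleosome-depleted region became 0.0903 in over against typical digestion, -0.0014 at 120 against 0 min and, turned, 0.0574 at 120 against 20 min. The +1 nucleosome became -0.0803 and -0.12 in over digestion and at 120 min. Turned values in over digestion were 0.0552 at -1, 0.0065 at +2, 0.013 at +3 and 0.0648 in mid-coding regions, and at 120 min 0.0770 at -1, 0.0741 in mid-coding regions and 0.0345 at the 3' end. Ribosomal protein coding regions in over digestion turned to a positive median, at percentile 98.32. The highest codon group became 0.11 and -0.0555 in over digestion and at 120 min. Coding regions called lower became 10 in over digestion, beside 81 higher, and 21 at 120 min. Nucleosome-depleted regions in over digestion split into 133 higher and 90 lower. Coding calls split 293 to 57 at 120 against 20 min, and 129 to 53 for 0 min against BY4741.

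Equal totals within each chromosome removes the excess of chromosome II at 20 min and of chromosome VIII against BY4741. At 20 min it left 47 higher nucleosome-depleted regions, 3 higher and 1 lower coding regions, and 0 of the extreme coding genes past the size rule. Coding calls split 224 to 47 at 120 against 20 min, and 17 to 73 for 0 min against BY4741. The +1 nucleosome became -0.19 at 120 min, and the -1 nucleosome -0.0024 there and -0.015 at 20 min. Mating coding regions lay at percentile 5.54 at 120 min and 2.72 in over digestion. Without chromosome II genes, 35 nucleosome-depleted and 2 coding regions were higher at 20 min. The nucleosome-depleted region had -0.13 at 20 min, -0.12 at 120 min and, turned, 0.0113 at 120 against 20 min. The totals used for scaling still included chromosome II. Its excess at 20 min lowers the other genes against 0 min and raises them at 120 against 20 min by construction. The larger loss and the turn are therefore not shown to be changes of those genes.

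Measured from the start codon, the nucleosome-depleted region had 0.12 in over digestion, -0.0017 at 20 min and, turned, 0.13 both at 120 against 0 min and at 120 against 20 min. It gave 173 and 113 higher genes in over digestion and at 20 min, and heat shock promoters at percentile 13.265. A window from 180 to 120 bp upstream gave -0.18, -0.18 and -0.36 in over digestion, at 20 and at 120 min. Leaving out genes with a shared promoter gave -0.0197, -0.0863 and -0.14. Reads without a mismatch gave -0.14 at 120 min and a +1 shift of 4.73 bp.

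Windows of 40 bp either side gave +1 shifts of 1.18, 1.64 and 2.89 bp, and 75 bp gave 3.07, 2.88 and 5.83 bp. Smoothing with 10 bp, which sharpens peaks by construction, gave peak-to-trough ratios of 5.43, 2.30, 6.29, 3.75 and 2.18, and spacings of 162.75 bp in over digestion and 169.25 bp at 120 min. Offsets searched from 60 bp gave a fragment of 94 bp in over digestion.

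A 1.5-fold rule calls more genes by construction. It gave 107 higher nucleosome-depleted regions at 20 min, and 269 higher and 119 lower coding regions in over digestion, 302 and 12 at 20 min, and 599 and 381 at 120 min. Libraries thinned to the smallest total gave 39 higher nucleosome-depleted regions in over digestion, 43 higher and 86 lower at 20 min, and 158 and 270 at 120 min, with 43 higher and 3 lower coding regions at 20 min and 63 lower at 120 min. At least 40 reads, which tests fewer genes, gave 45 higher and 53 lower in over digestion, 26 and 81 at 20 min, and 152 higher at 120 min, and a promoter similarity of over digestion with 20 min of r = 0.124. At least 10 reads gave 135 higher at 20 min.

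Centring by GC content left 7 higher coding regions in over digestion, 13 higher and 54 lower at 120 min, and 169 higher nucleosome-depleted regions at 120 min. Against random lists matched on GC content, coding percentiles were 35.17 for glycolysis and 95.925 for ribosomal protein genes in over digestion, and at 120 min 46.605 for glycolysis, 29.53 for heat shock, 56.455 for PAU and 25.145 for meiosis genes. Retrotransposons were planned as a class of loci and were not run.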

Other observations

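Marker genes that laboratory strains often lack differed between the strains. They were chosen after their values were seen. LEU2 and MET17, genes of leucine and methionine synthesis, had 0 reads in both BY4741 libraries, where the genome mean would give 104 and 127 reads in typical digestion. In rpb1-1 LEU2 had 162, 115 and 151 reads and MET17 had 350, 300 and 337 at 0, 20 and 120 min. URA3, a gene of uracil synthesis, had 0 reads in typical digestion, at most 4.83% of the genome mean, but 42 in over digestion, 19.8% of the genome mean (14.3% to 26.7%), although both libraries carry the same strain label. In rpb1-1 it had 252, 167 and 190 reads. HIS3, TRP1 and LYS2, genes of histidine, tryptophan and lysine synthesis, had reads in all 5 libraries.

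Mitochondrial reads were rare and uneven. There were 27 in typical digestion, 2533 in over digestion, and 4, 1073 and 20 at 0, 20 and 120 min. Mapped reads covered 16.05% of the bases of the mitochondrial sequence, against at least 80.4% for each nuclear chromosome.

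In the background comparison of rpb1-1 at 0 min with BY4741 typical digestion, coding regions of glycolysis, heat shock and ribosomal protein genes were lower in rpb1-1, with median log2 ratios of -0.58, -0.37 and -0.40 at percentiles 0, 0 and 0.01. The median of 10 histone genes was -1.24, at percentile 0.01, and that of 4 PAU genes -1.50, at percentile 0.89. Meiosis genes had a median of 0.00096, at percentile 100, which became 72.485 when random lists were also matched on GC content, a setting chosen after seeing the data. The tRNA genes were 2.10-fold higher and the 9 centromeres 1.41-fold higher in rpb1-1. Alignment errors are scored differently in the files of the strains, and the treatment of reads with several matches is not given. Differences in alignment, above all of repeated sequence, are therefore not separated from strain in these ratios. The GC content of the coding region had r = -0.374 with this ratio across 5012 genes.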
